A study of Mus musculus with 8 samples.

How the data were processed

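Gene expression was measured in superior cervical ganglia, the sympathetic ganglia of the neck, taken from mice on postnatal day 0. Bax null ganglia were compared with ganglia null for both Ngf and Bax. Bax is a protein needed for the programmed death of developing neurons, and its deletion keeps neurons alive that lack nerve growth factor (NGF). Total RNA was isolated on silica columns, amplified in 1 round from a T7 promoter and labelled with biotin, per the labels' protocols. Each of 2 samples per genotype was hybridised to 2 Affymetrix array types, 430A and 430B, which gave 8 arrays in 4 groups of 2. The labels do not say whether a sample was 1 animal or a pool, or that the samples came from separate animals. The p-values therefore measure only the spread between these samples, which may be technical.

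The deposited values are array intensity on a linear scale, 1 MAS5 signal per probe set, made with GCOS 1.4 and MAS5 per the submitters' processing notes. The mean of the deposited intensity values, after the lowest and highest 2% of probe sets were set aside, lay at 150.0 or 150.1 on every array, so all arrays had been scaled to one level. Such scaling removes any difference in total signal between samples. The table held no detection calls, and the genome build behind the probe sets is not given in the sources used here. The number of arrays limits the precision. All value columns were used.

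Probe sets were named from the platform annotation given with the data, which dates from 2016, with symbols updated through gene identifiers of the GRCm38.p6 annotation. On 430A, 20393 probe sets listed 1 gene, 691 listed several and 1555 were not listed. On 430B these numbers were 14674, 245 and 7605. No name was taken from a probe set that listed several genes, and a probe set that was not listed is unnamed here, not without a gene. A gene was represented by its probe set with the highest mean signal, with the cross-hybridising type (suffix _x_at) taken only where there was no other.

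The following choices were made before the data were examined. Signals were transformed as log2(signal + 32), control probe sets were set aside, and the 40% of probe sets with the lowest mean were left out. This left 13576 probe sets and 8616 named genes on 430A, and 13507 and 6846 on 430B. A fold change is on the log2(signal + 32) scale and understates the change of dim genes. Each array type was fitted on its own with limma 3.58.1 in R 4.3.3, with moderated variances that follow an intensity trend, and p-values were adjusted by the Benjamini-Hochberg method over the probe sets kept on that type. The threshold was an adjusted p of 0.05, and all tests were two-sided. As a description without a test, probe sets were counted whose 2 groups did not overlap and differed by at least 2-fold. Chance alone sets the 2 groups apart in 33.3% of probe sets. A permutation test of single values was not used, because 2 arrays against 2 allow no p under 0.333.

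A total of 34 gene lists with 681 entries was fixed by hand, of which 2 symbols had no match. Lists with at least 5 measured genes were tested with limma's camera at a preset correlation between genes of 0.01, with camera at an estimated correlation and the rotation test fry beside it, and adjusted over the lists of an array type. The genes named in the text follow a rule fixed at the same time. It took the 12 genes with the largest rise and the 12 with the largest fall on 430A, and 6 and 6 on 430B, among genes past the threshold with groups that did not overlap. Where fewer than 5 passed in a direction, it filled up from genes with an unadjusted p under 0.01, a difference of at least 2-fold and groups that did not overlap. It also took Ngf, Bax, Ntrk1, Ngfr, Bdnf, Th and Dbh, and 2 to 4 members of each list described, those with the largest change among members past the threshold or, where none passed, among all measured members.

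The procedure was tested on simulated data with the real means and spreads, in 10 draws with 200 changed probe sets each. Noise was drawn for each probe set on its own, with no correlation between genes and no effect of the sample number. Recovery in the real data may therefore differ. Of the 2-fold changes, 46.7% were recovered among 13576 probe sets on 430A and 13.7% among 13507 on 430B, and of the 4-fold changes 99.8% and 83.9%. A simulated shift of 0.4 in the synaptic vesicle list was called with the preset correlation in 9 of 10 draws on 430A and in 4 of 10 on 430B, and with the estimated correlation in 0 of 10 on both. Alternatives covered the pseudocount, the filter, the normalization, the variance model, a block for the sample number, the probe set that stands for a gene and the omission of each array in turn. List calls under these alternatives used the preset correlation, and with the block or without an array no other was run. Python 3.11 and matplotlib were used for the plots.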

Results

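Superior cervical ganglia of newborn mice were profiled in 2 genotypes, Bax null and Ngf-Bax double null, with 2 samples per genotype on each of 2 array types. The comparison addressed which transcripts in sympathetic ganglia depend on NGF when the neurons are kept from dying by the loss of Bax. The median signal of the 4 arrays ranged from 65.5 to 70.8 on 430A and from 82.7 to 91.4 on 430B. Log2 signals of the 2 Bax null arrays correlated at r = 0.946 across probe sets on 430A and at 0.858 on 430B, and those of the 2 double null arrays at 0.937 and 0.851. Between genotypes they ranged from 0.926 to 0.953 on 430A and from 0.832 to 0.872 on 430B, ranges that take in the values within genotypes. On 430A the highest were between arrays numbered alike, at 0.947 for samples 1 and 0.953 for samples 2. On 430B samples 2 had the highest, at 0.872, but samples 1 stood at 0.851. These correlations are across probe sets, which are not independent replicates. The signal of the 5' over the 3' control probe set, a sign of RNA quality, stood apart between genotypes for Gapdh on 430A (0.241 and 0.254 in Bax null, 0.222 and 0.183 in double null) and for actin on 430B (0.312 and 0.388, 0.255 and 0.304). It overlapped for Gapdh on 430B (0.204 and 0.245, 0.148 and 0.206) and for actin on 430A (0.279 and 0.380, 0.216 and 0.291). How these ratios bear on the lists below was not tested. Log2 changes below are double null minus Bax null, with the standard error of the limma fit and 2 arrays per group.

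The genes altered in these mice could not be read, because Ngf, Bax and the NGF receptor gene Ntrk1 had 0 probe sets that listed them alone, so the labels were not checked by the targeted genes. Genes known to respond to NGF were lower as a group in double null ganglia. On 430A the list of NGF-responsive genes fell by 0.47 on average over 11 measured genes, 8 of which were lower (camera, adjusted p = 0.0085, and adjusted p = 0.57 with an estimated correlation, where the call was lost). On 430B it fell by 0.70 on average over 6 genes, all 6 lower, but the median was -0.29 (camera, adjusted p = 0.027, lost at adjusted p = 0.62 with an estimated correlation). The largest differences were in Vgf, a secreted neuropeptide precursor, at -1.81 ± 0.44, in Coro1a, an actin-binding protein, at -1.70 ± 0.44, in Islr2, a membrane protein of growing axons, at -1.65 ± 0.55, and in Ngfr, the p75 neurotrophin receptor, at -1.36 ± 0.43. On 430B only 2 of the 6 members, Vgf and Islr2, had groups that did not overlap, and Tac1 was at -0.04. Islr2 also belongs to the axon growth list. Th, tyrosine hydroxylase, the rate-limiting enzyme of noradrenaline synthesis, had a signal of 1879 ± 300 (SD, n = 2) in Bax null and 884 ± 414 (SD, n = 2) in double null ganglia, a log2 change of -1.13 ± 0.33. Single arrays carried much of some of these values, which came to -0.91 for Coro1a and -0.65 for Th without double null sample 1, and to -0.70 for Ngfr and -0.96 for Islr2 without Bax null sample 1. A second kept probe set of Coro1a was at -0.79. The list drew in part on later work on NGF-deprived neurons, some of which may rest on these samples, so it is not independent evidence of its direction. None of these genes passed the threshold over all probe sets, while 5 of the 11 members on 430A and 2 of the 6 on 430B passed when adjusted over the list alone. Among those 5, the neuropeptide Npy ran the other way, at 1.04 ± 0.33, and at 0.55 without double null sample 2. On 430A the call was also lost without Bax null sample 1 (mean -0.30, adjusted p = 0.14) and without double null sample 1 (mean -0.29, adjusted p = 0.090), and on 430B it could not be tested without Bax null sample 1, or with the lowest 60% left out, where fewer than 5 members were measured. The lower 5' to 3' ratios in double null arrays, of Gapdh on 430A (0.222 and 0.183 against 0.241 and 0.254) and of actin on 430B (0.255 and 0.304 against 0.312 and 0.388), went with these lower signals.

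**Figure D1:**
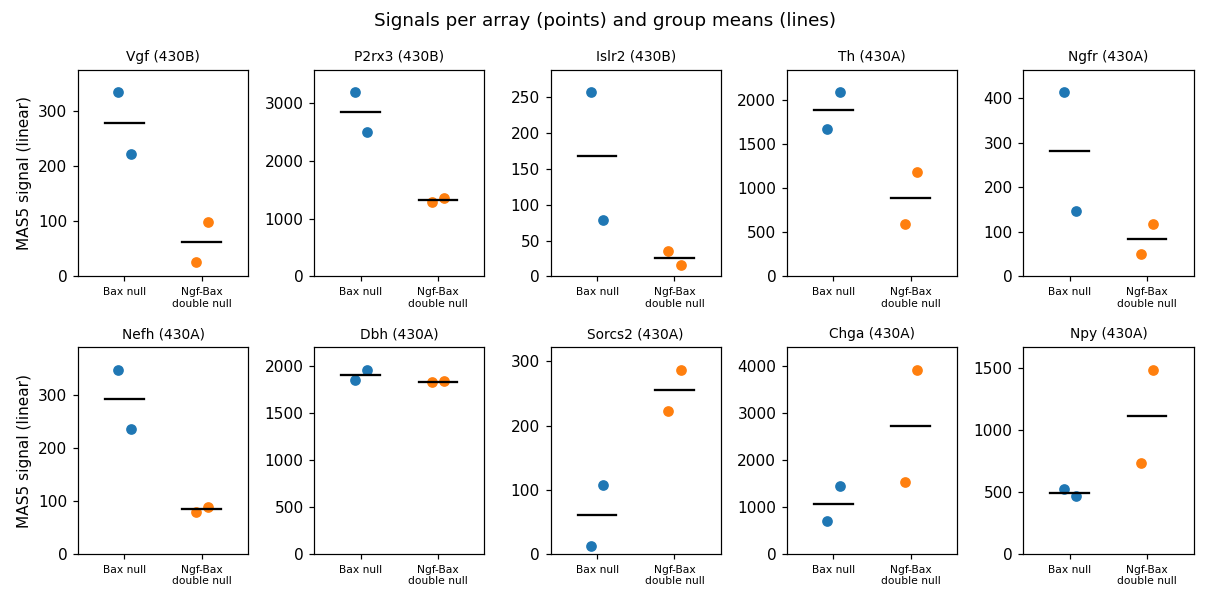
Signal (linear MAS5 units, vertical axis from 0) of 10 genes on each array of the type named above each panel, for Bax null and Ngf-Bax double null ganglia; points are single arrays and black lines group means of 2 arrays. The arrays of both genotypes lie apart for every gene drawn. For Dbh the group means are close, at 1904 and 1830. The genes drawn are a selection and do not show how often the genotypes lie apart. Over all kept probe sets the groups did so in 32.9% on 430A and 32.03% on 430B, where chance gives 33.3%.

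Other genes of the sympathetic transmitter had values in both directions, none past the threshold. Dbh, dopamine beta-hydroxylase, stood at 1904 ± 78.3 in Bax null and 1830 ± 12.6 in double null ganglia on 430A (SD, n = 2), a log2 change of -0.05 ± 0.23. Chga, chromogranin A, a protein of secretory granules, was at 1.26 ± 0.45 and did not pass, and was at 0.59 without double null sample 2. The list of catecholamine synthesis and storage genes had a mean of -0.06 over 13 genes on 430A (adjusted p = 0.59) and of -0.03 over 5 on 430B (adjusted p = 0.99). On 430B the largest values were in Slc6a2, the noradrenaline transporter, at -0.86 ± 0.39, and Ddc, dopa decarboxylase, at 0.78 ± 0.31. Neurotrophin and growth factor signalling genes had a mean of -0.08 over 17 genes on 430A (adjusted p = 0.83) and -0.15 over 8 on 430B (adjusted p = 0.81). Within it, Gfra3, a GDNF family receptor subunit, was at 0.62 ± 0.31 on 430A. The receptor Ret was at -0.53 ± 0.25 on 430A and -1.13 ± 0.38 on 430B, and Ntrk3 at 0.17 ± 0.24 and -0.39 ± 0.37, in opposite directions. Bdnf was dim, at 58.1 ± 19.5 and 51.2 ± 46.7 (SD, n = 2), with a log2 change of -0.22 ± 0.40. A second Bdnf probe set, left out by the filter and also dim, was lower in double null ganglia. Its signals were 58.3 and 47.3 in Bax null and 4.9 and 17.4 in double null arrays. Sympathetic neuron transcription factors had a mean of 0.09 over 9 genes (adjusted p = 0.66), with Phox2a at 0.51 ± 0.38 and Hand1 at -0.45 ± 0.27. Single arrays carried much of several values. Bdnf was at 0.39, Phox2a at -0.022 and Gfra3 at 0.30 without double null sample 2, and Ret on 430B was at -0.53 and Hand1 at -0.18 without Bax null sample 1. Ntrk3 on 430B was at 0.095 without double null sample 1, and Ddc at 0.47 and Dbh at -0.014 on 430A without Bax null sample 2.

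Markers of sensory neurons, among them those of the nodose ganglion, showed the largest mean shift of any list tested. This list fell by 0.91 on average over 6 genes on 430A, 5 of them lower. It passed in camera at the preset correlation (adjusted p = 1.0e-06), and the call was lost with an estimated correlation (adjusted p = 0.57). Without each of the 4 arrays in turn its mean ranged from -1.06 to -0.76. Nefh, the heavy neurofilament subunit, was at -1.46 ± 0.25, Slc17a6, a vesicular glutamate transporter, at -1.39 ± 0.32, and the homeobox gene Hoxb5 at -1.33 ± 0.27. Of the 6 genes, 4 passed when adjusted over the list alone and 0 over all probe sets. Nefh also belongs to the axon growth list and Tlx3 to the cholinergic list. On 430B only 4 members were measured, too few for a test, with a mean of -0.45. P2rx3, an ATP-gated channel, was at -1.08 ± 0.26, Pou4f1 at -0.79 ± 0.54, Trpv1 at -0.50 ± 0.30 and Prrxl1 at 0.56 ± 0.43, and without double null sample 2 Pou4f1 was at 0.16. The Gapdh 5' to 3' ratio on 430A, at 0.222 and 0.183 in double null against 0.241 and 0.254 in Bax null arrays, was lower along with the list.

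Synaptic vesicle genes fell by 0.24 on average over 16 genes on 430A, 14 of them lower (adjusted p = 0.0080, and adjusted p = 0.59 with an estimated correlation, where the call was lost). On 430B they fell by 0.36 over 9 genes (adjusted p = 0.027, lost at adjusted p = 0.62 with an estimated correlation). Syt4 was at -0.71 ± 0.24, Sncg, gamma-synuclein, at -0.62 ± 0.25 and Syn2, a synapsin, at -0.53 ± 0.23 on 430A, and Syn2, Syt1 and Rab3c at -0.87 ± 0.27, -0.85 ± 0.30 and -0.59 ± 0.28 on 430B. Pan-neuronal genes fell by 0.22 over 14 genes (adjusted p = 0.021, lost at adjusted p = 0.57 with an estimated correlation), with the neuronal enolase Eno2 at -0.77 ± 0.23, Thy1 at -0.68 ± 0.29 and Stmn3 at -0.47 ± 0.23. The axon growth and cytoskeleton list fell by 0.45 over 8 genes on 430B (adjusted p = 0.027, lost at adjusted p = 0.62 with an estimated correlation), with Islr2, the light neurofilament subunit Nefl at -0.97 ± 0.38 and Mapt, the tau gene, at -0.49 ± 0.28. On 430A it did not pass, with a mean of -0.15 over 25 genes, 9 higher and 16 lower (adjusted p = 0.27). It passed under quantile normalization (mean -0.21, adjusted p = 0.029) and with spike-in centring (mean -0.61, adjusted p = 0.0013). Its mean was -0.23 without Bax null sample 2, but -0.066 without double null sample 1 and -0.11 without Bax null sample 1. Its members Coro1a, Nefh, Nefl at -1.12 ± 0.24 and Nefm at -0.99 ± 0.28 passed on 430A when adjusted over the list alone, and no member of these lists passed over all probe sets. Without Bax null sample 1 the 4 calls were lost, with means of -0.21 for vesicles and -0.17 for pan-neuronal genes on 430A (adjusted p = 0.15 and 0.33) and of -0.23 for vesicles and -0.18 for axon growth on 430B (adjusted p = 0.43 and 0.65). Without double null sample 1 the vesicle list on 430A and the axon growth list were lost (means -0.16 and -0.40, adjusted p = 0.19 and 0.18). Without double null sample 2 the pan-neuronal list, the vesicle list on 430B and the axon growth list were lost (means -0.16, -0.30 and -0.51, adjusted p = 0.33, 0.21 and 0.092). On 430B both calls were also lost without the filter (adjusted p = 0.053 and 0.074), and the axon growth call with the lowest 60% left out (adjusted p = 0.14). Among the genes named, Thy1 and Mapt were at -0.31 and -0.30 without double null sample 1, and on 430B Nefl, Islr2 and Rab3c at -0.54, -0.96 and -0.30 without Bax null sample 1. These lists were lower along with the 5' to 3' ratios of Gapdh on 430A (0.222 and 0.183 against 0.241 and 0.254) and of actin on 430B (0.255 and 0.304 against 0.312 and 0.388).

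**Figure D2:**
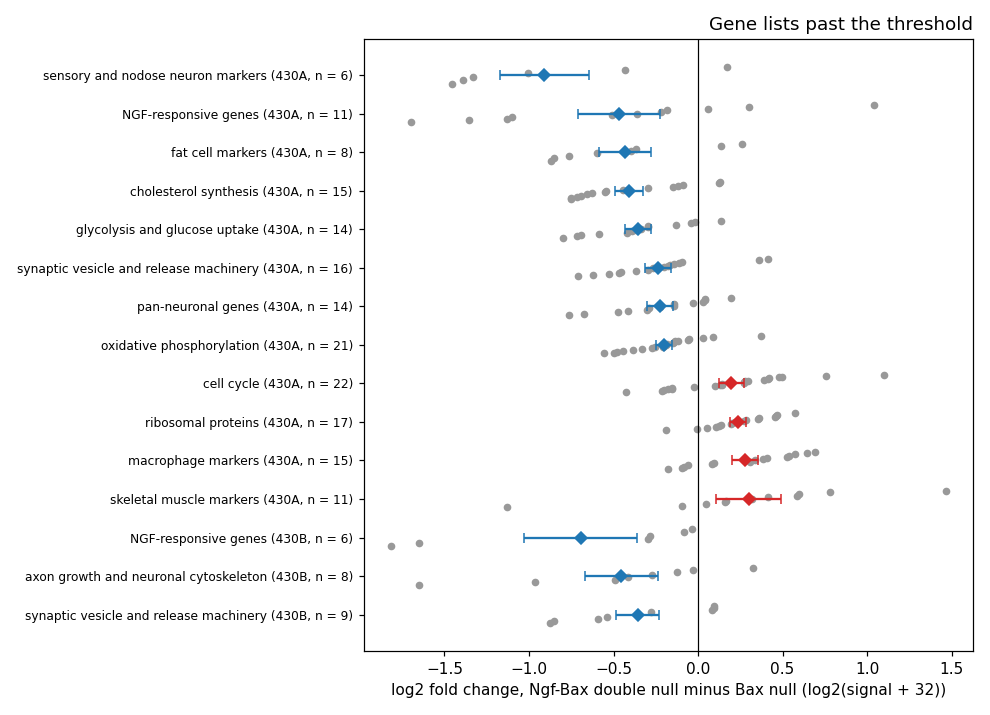
Log2 fold change on the log2(signal + 32) scale (horizontal axis, double null minus Bax null) for each gene list past the threshold on 430A or 430B; grey points are the member genes, diamonds the list means and bars the standard error over members. The sensory neuron list lies lowest, at -0.91, and the skeletal muscle list highest, at 0.30.

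Cholesterol synthesis genes fell by 0.41 on average over 15 genes on 430A, 13 of them lower (adjusted p = 3.0e-05, and adjusted p = 0.57 with an estimated correlation, where the call was lost), with Idi1 at -0.75 ± 0.26, Nsdhl at -0.75 ± 0.26 and Fdps, farnesyl diphosphate synthase, at -0.72 ± 0.23. Glycolysis genes fell by 0.35 over 14 genes, 13 of them lower (adjusted p = 0.00035, lost at adjusted p = 0.59 with an estimated correlation), with Ldha, lactate dehydrogenase, at -0.80 ± 0.27, Pgk1 at -0.72 ± 0.27 and Aldoa, an aldolase, at -0.69 ± 0.29. Oxidative phosphorylation genes fell by 0.20 over 21 genes, 18 of them lower (adjusted p = 0.013, lost at adjusted p = 0.57 with an estimated correlation), with Atp5b at -0.56 ± 0.36, Sdha at -0.50 ± 0.24 and Cycs at -0.48 ± 0.29. Without each array in turn the mean of the cholesterol list ranged from -0.58 to -0.26, closest to 0 without double null sample 1. Glycolysis was lost without double null sample 1 (mean -0.19, adjusted p = 0.13), and oxidative phosphorylation without Bax null sample 1, double null sample 1 or double null sample 2 (adjusted p = 0.14, 0.12 and 0.071), where its mean stayed near its value, at -0.20, -0.16 and -0.23. Fat cell markers moved with these lists. They fell by 0.43 over 8 genes (adjusted p = 0.013, lost at adjusted p = 0.70 with an estimated correlation), with the adipocyte hormone Adipoq at -0.87 ± 0.30, Car3 at -0.85 ± 0.34 and Ucp1, the uncoupling protein of brown fat, at -0.76 ± 0.35. That call was also lost without double null sample 1 (mean -0.13, adjusted p = 0.47) and without Bax null sample 2 (mean -0.33, adjusted p = 0.067), and the mean was -0.74 without double null sample 2. Most of the genes named here leaned on single arrays. Idi1 was at -0.50, Ldha at -0.50, Aldoa at -0.34, Adipoq at -0.52, Car3 at -0.30 and Ucp1 at -0.21 without double null sample 1. Pgk1 was at -0.41 and Cycs at -0.14 without Bax null sample 1, and without Bax null sample 2 Atp5b was at -0.085. The signal of the 5' over the 3' Gapdh control probe set on 430A was 0.241 and 0.254 in Bax null and 0.222 and 0.183 in double null arrays.

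Ribosomal protein, macrophage, cell cycle and skeletal muscle genes were higher on 430A under the submitters' scaling, and all 4 list means were below 0 when arrays were centred on the spike-in controls, which moved the median of all probe sets to -0.46. Relative to other genes these lists were still higher with that centring. Macrophage markers rose by 0.28 over 15 genes, 11 of them higher (adjusted p = 0.0027, and adjusted p = 0.57 with an estimated correlation, where the call was lost), with the complement genes C1qb at 0.69 ± 0.28 and C1qc at 0.64 ± 0.28 and the receptor Csf1r at 0.57 ± 0.25. Ribosomal protein genes rose by 0.24 over 17 genes, 15 of them higher (adjusted p = 0.0063, lost at adjusted p = 0.57 with an estimated correlation), with Rpl27a at 0.57 ± 0.64, Rps14 at 0.47 ± 0.24 and Rpl4 at 0.46 ± 0.22, and this call was lost under quantile normalization (mean 0.13, adjusted p = 0.15). Cell cycle genes rose by 0.20 over 22 genes, 15 of them higher (adjusted p = 0.020, lost at adjusted p = 0.61 with an estimated correlation), with Ccnd1, cyclin D1, at 1.10 ± 0.31, Bub1b at 0.76 ± 0.29 and Mcm6 at 0.49 ± 0.24. Skeletal muscle markers rose by 0.30 over 11 genes (adjusted p = 0.020, lost at adjusted p = 0.77 with an estimated correlation), with Tnnc2 at 1.47 ± 0.50 and Acta1 at 0.78 ± 0.41 but Myl1 at -1.13 ± 0.41. Macrophage markers were also lost without double null sample 2 (mean 0.17, adjusted p = 0.18), and muscle markers without Bax null sample 1 (mean 0.17, adjusted p = 0.24) and double null sample 1, where the mean turned to -0.22 (adjusted p = 0.42). The muscle mean was 0.46 without Bax null sample 2 and 0.62 without double null sample 2. Ribosomal genes were lost without Bax null sample 1, Bax null sample 2 or double null sample 1 (adjusted p = 0.064, 0.067 and 0.12), with means of 0.24, 0.24 and 0.17. Cell cycle genes were lost without Bax null sample 2, double null sample 1 or double null sample 2 (means 0.084, 0.21 and 0.13, adjusted p = 0.62, 0.086 and 0.33) and with a pseudocount of 1 (adjusted p = 0.054), and their mean was 0.30 without Bax null sample 1. With that pseudocount, the lowest 60% left out or the sample number as a block, muscle markers were lost too (adjusted p = 0.080, 0.34 and 0.067). Tnnc2 was at 0.60, Acta1 at 0.10, Rps14 at 0.25 and Rpl27a at -0.46 without double null sample 1. C1qb and C1qc were at 0.37 and 0.31 without Bax null sample 1, and without double null sample 2 Myl1 was at -0.44. The Gapdh 5' to 3' ratio on 430A was 0.222 and 0.183 in double null and 0.241 and 0.254 in Bax null arrays.

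The other lists did not pass in camera with all arrays on either type. On 430B axon guidance genes and receptors and channels passed fry's test for change in either direction (adjusted p = 0.028 for both), which does not compare a list with other genes. Satellite glia and Schwann cell markers had a mean of 0.00 over 16 genes (adjusted p = 0.87), with Foxd3 at 0.83 ± 0.24 and Mbp, myelin basic protein, at -0.81 ± 0.32. The 7 kept probe sets of Mbp disagreed, from -1.24 to 0.17. Fibroblast, endothelial and mural, and lymphocyte, neutrophil and mast cell markers had means of 0.09, 0.02 and 0.06 (adjusted p = 0.42, 0.87 and 0.52), and carotid body and chromaffin markers 0.07 (adjusted p = 0.87). Immediate early genes had a mean of -0.14 over 22 genes (adjusted p = 0.42), with Fos at -1.55 ± 0.49 and Nr4a3 at -0.98 ± 0.30, and on 430B -0.08 over 7 (adjusted p = 0.84). Injury and stress response genes were at 0.16 (adjusted p = 0.083), with Cdkn1a, the p21 inhibitor, at 0.86 ± 0.25 and Atf5 at 0.62 ± 0.33. The list passed with the mean of all kept probe sets (adjusted p = 0.039). Its mean was 0.24 without Bax null sample 2, but 0.082 without Bax null sample 1 and 0.078 without double null sample 2. Apoptosis regulators were at 0.12 on 430A and 0.18 on 430B (adjusted p = 0.26 and 0.56), with the prolyl hydroxylase Egln3 at 1.28 ± 0.24 and Bcl2l11, the BH3-only protein Bim, at 0.61 ± 0.24. Axon guidance genes were at -0.18 on 430A and 0.10 on 430B (adjusted p = 0.083 and 0.56). On 430A their mean was -0.30 without Bax null sample 2, but -0.051 without Bax null sample 1. The adhesion molecule Chl1 was at -0.95 ± 0.25 on 430A and -1.29 ± 0.31 on 430B, and Efnb2 at -0.88 ± 0.44 on 430A. Dcc was at -0.06 ± 0.23 on 430A and 1.05 ± 0.28 on 430B. Receptors and channels were at -0.17 and -0.11 (adjusted p = 0.26 and 0.91), with the serotonin receptor Htr3a at -1.04 ± 0.25 on 430A. Chrnb4 was at -0.41 ± 0.29 on 430A and 0.11 ± 0.27 on 430B. The ATP-gated channel P2rx2 and Scn2b were at -2.14 ± 0.44 and -0.73 ± 0.36 on 430B. Efnb2 was at -0.098, Chrnb4 on 430A at -0.083 and Atf5 at 0.11 without double null sample 2, and Mbp was at -0.37 and Nr4a3 at -0.63 without double null sample 1. Fos was at -0.74 without Bax null sample 2, and Scn2b at -0.24 without Bax null sample 1.

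Cholinergic genes had a mean of -0.16 over 6 genes (adjusted p = 0.45), with Ache, acetylcholinesterase, at -1.08 ± 0.27 and Tlx3 at -0.43 ± 0.24. Neuropeptides had a mean of -0.10 over 10 genes (adjusted p = 0.59), with Tac1, the substance P precursor, at -1.10 ± 0.32 on 430A but -0.04 ± 0.31 on 430B, and Npy at 1.04 ± 0.33 on 430A. Interferon response genes had a mean of -0.11 over 11 (adjusted p = 0.62), with Oas1a at -1.38 ± 0.26 and Ifit3 at 0.43 ± 0.26. Without double null sample 2, Tac1 on 430A was at -0.71 and Npy at 0.55, without double null sample 1 Tlx3 was at -0.26, and without Bax null sample 1 Ifit3 was at 0.23. SRF target genes and BMP and TGF beta response genes had means of -0.04 and -0.09 (adjusted p = 0.83 and 0.59). The 14 measured neighbours of Ngf on its chromosome had a mean of 0.01 on 430A (adjusted p = 0.83), and the 13 on 430B a mean of -0.05 (adjusted p = 0.91). On 430B, cell cycle genes had a mean of 0.34 over 5 (adjusted p = 0.24), and passed with the mean of all kept probe sets (adjusted p = 0.043). Red blood cell markers and sex-linked genes had 4 and 3 measured genes on 430A, too few for a test, with means of -0.06 and -0.25. On 430B another 20 lists had 1 to 4 measured genes and were not tested, with means from -0.57 for 2 endothelial and mural cell markers to 0.51 for 4 sympathetic transcription factors. The 1 macrophage marker and the 1 ribosomal protein gene measured there were at -0.43 and -0.24. The mean and the median differed in sign for 3 lists on 430A and 2 on 430B, none of them past the threshold.

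Among single genes on 430A, the largest differences were lower signals in double null ganglia. The largest were in St6galnac5, a sialyltransferase, at -2.10 ± 0.27, Chst15, a sulfotransferase, at -2.09 ± 0.24, and the heat shock gene Hspa1b at -1.94 ± 0.29. Signals of St6galnac5 were 610 ± 21.1 in Bax null and 121 ± 44.8 in double null ganglia (SD, n = 2). The others that the rule took were Coro1a, Ntng1, Rspo2, Unc5b, H2-T3, Nefh, Hspa1a, Olfm1 and Mab21l1, from -1.70 to -1.40. Hspa1a and Hspa1b are near-identical copies that their probes may not separate. The higher genes were Sorcs2, a sorting receptor, at 1.85 ± 0.45, and Trpd52l3, Pdlim3, Fank1, Nfe2l3, Crim1, Sytl4, Egln3, Rimklb, Kalrn, Frmd4b and Spata5, from 1.58 to 1.18. None passed the threshold, and the lowest adjusted p was 0.069, for a second probe set of Hspa1b at -2.23 ± 0.24. Kept probe sets of Fank1, Kalrn and Spata5 disagreed in sign. Other kept probe sets lay much nearer 0 for Unc5b, at -0.17, H2-T3, at -0.16, Ntng1, at -0.31 and -0.43, and Nfe2l3, at 0.49. Without Bax null sample 1 Sorcs2 was at 1.04 and Fank1 at 0.93, and without Bax null sample 2 Spata5 was at 0.67. Without double null sample 1 Coro1a was at -0.91, Olfm1 at -0.71, Frmd4b at 0.67 and Rimklb at 0.82.

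On 430B the higher genes were Fbxo41 at 2.30 ± 0.27, Cbln2, a synaptic organiser, at 2.22 ± 0.28, and Abca9, Syndig1, Kcnc1 and Edem2, from 1.89 to 1.64. The lower genes were P2rx2, Ralyl, Ppp1r1c, Lypd1, Ube2ql1 and Grm7, from -2.14 to -1.95. None of these passed, with a lowest adjusted p of 0.117. Kept probe sets of Kcnc1, Edem2 and Ube2ql1 disagreed in sign. Others lay nearer 0 for Grm7, at -0.14, Abca9, at 0.19, Fbxo41, at 0.56, and Lypd1, at -0.66 on 430A. St6galnac5 was also lower on 430B, at -0.99 ± 0.24, as was Chl1. These were the 2 genes with an unadjusted p under 0.01 on both array types, chosen after their values were seen. Of the 29 genes with such a p on 430A, 17 had the same sign on 430B, and of the 17 on 430B, 7 had the same sign on 430A.

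Over all probe sets, limma called 0 of 13576 on 430A and 0 of 13507 on 430B. An unadjusted p under 0.05 was reached by 743 on 430A, where chance gives 679, and by 693 on 430B, where chance gives 675. Groups that did not overlap and differed by at least 2-fold were found for 131 probe sets on 430A, 44 higher and 87 lower, and for 444 on 430B, 211 higher and 233 lower. Centred on the spike-in controls, these splits became 2 higher and 564 lower, and 43 higher and 675 lower. The 2 groups did not overlap in 32.9% of probe sets on 430A and 32.03% on 430B, where chance gives 33.3%. The log2 changes of 1995 genes measured on both types by different probe sets correlated at r = 0.144 (95% interval 0.101 to 0.187) and rho = 0.138 across genes, which are not independent replicates. The sign was the same for 53.3% of them. Both types carried samples of the same names, so differences between samples alone give a correlation, and the 2 other splits of the 4 samples gave r = 0.0691 and 0.0816. Other settings and single arrays decided these counts in part. With the sample number as a block, which the labels do not pair, limma called 2 probe sets on 430A and 101 on 430B. With 4 arrays the block leaves little from which to estimate the spread, so these calls are not evidence of single-gene differences. Centred on the spike-in controls, limma called 21 and 8, all lower. Without Bax null sample 2, double null sample 1 or double null sample 2, limma called 15, 6 and 20 probe sets on 430A, and without either double null sample 5 and 30 on 430B. Of the lists, 12 of 32 passed on 430A and 3 of 11 on 430B, and 0 on either type with an estimated correlation or in fry's directional test. Without Bax null sample 1, 6 and 0 lists passed on 430A and 430B, without double null sample 1 it was 4 on 430A, and without double null sample 2 it was 1 on 430B. In the first of these fits 1 of the 3 lists called on 430B, that of NGF-responsive genes, could not be tested. Fry's test for change in either direction passed for 0 lists on 430A and 2 on 430B, axon guidance and receptors and channels.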

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

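The tests of single arrays and of fat tissue below were chosen after the result they measure was seen, as was the upper limit required in the test of a strain haplotype, and the others before.

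Some control probe sets outside the comparison stood apart between the genotypes on both array types, and 3 did so with higher signals in double null arrays. Of 32 controls above the filter on 430A, 12 stood apart higher and 3 lower, and of 36 on 430B, 5 and 4. The bacterial spike-in control BioB-5 was higher in double null arrays by 0.49 on the log2(signal + 32) scale on 430A and by 0.43 on 430B. Its signals on 430A were 225.7 and 213.7 in Bax null and 343.5 and 299.4 in double null arrays. Of the 18 spike-in probe sets, 9 stood apart on 430A but 1, BioB-5, on 430B, though the means of all 18 were higher on both types, by 0.37 to 0.59 and by 0.041 to 0.49. The 18S ribosomal RNA 3' control was higher by 0.35 on 430A and 0.48 on 430B, and the B2 repeat control by 0.52 and 0.29. The 5' control of 18S stood apart on neither type, and a second B2 control only on 430B. Chance sets 2 groups of 2 apart in 33.3% of probe sets. All 3 Gapdh controls were lower on both array types, from -0.31 to -0.59 on 430A and from -0.50 to -0.84 on 430B.

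Sensory and nodose neuron markers were lower in double null ganglia, by -0.91 on average on 430A. The tables argue against a single array as the cause, because the mean stayed at -0.76 or below without each of the 4 arrays. Sensory ganglion tissue carried into the Bax null samples stays open and cannot be told apart here. A second sensory list, written before its values were seen, had a median of -0.18 over 7 measured genes of 26. The standard error of their mean was 0.18. All 7 were lower, from Eya1 at -0.04 to Htr3b at -1.32, with Ldhb at -0.18 (mean signals 903 and 787). The loss of NGF, which the design names, also stays open, as untested.

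Hspa1a and Hspa1b were lower in double null ganglia, at -1.45 and -1.94. Heat shock or handling stress in the Bax null samples predicts that other targets of the heat shock factor fall with them. Their median was -0.16 over 15 genes, above the -0.5 set beforehand, and the standard error of their mean was 0.075. This argues against a fall of that size over these targets as a set. It cannot exclude stress that moved Hspa1a and Hspa1b more than the others. Of the 15, 12 were lower, with Hsph1 at -0.81 and Hspa8 at -0.57. A strain haplotype around the locus cannot be told apart. Of 50 measured neighbours, 2% had an unadjusted p under 0.05, against 5.28% of all genes. Only 5.83% of such windows around all measured genes had a smaller share, below the 50th percentile set beforehand against a haplotype. The count is too small to exclude the overall share (upper limit 10.6%), so it decides nothing. The loss of NGF stays open, as untested.

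Cholesterol, glycolysis and oxidative phosphorylation genes were lower together, by -0.31 on average over 50 genes. The mean came closest to 0 without double null sample 1, at -0.20, which argues against that array as the whole cause. Less fat tissue in the double null samples cannot be told apart. Between the samples numbered 2 the difference was 0.46 of that between the samples numbered 1, and for fat cell markers 0.25, but the numbers do not pair the samples, so these ratios decide nothing. The genotype stays open, as untested.

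With 2 arrays per group, the 4 arrays of a type can be split in only 3 ways, too few for a share under 0.05. The count of 0 probe sets past the threshold, also 0 in the other splits, cannot be compared, because any split gives at least 0. For consistent 2-fold differences the genotypes gave 131 against 163 on 430A and 444 against 460 on 430B, both from the split by sample number. That split also gave 433 probe sets on 430A and 226 on 430B with an unadjusted p under 0.01, against 194 and 148 for the genotypes. For lists past the threshold the genotypes gave 12 against 3 on 430A and 3 against 0 on 430B, but only at the preset correlation. With an estimated correlation all 3 splits gave 0 on both types.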

How the results depend on the processing

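The centring on spike-in controls, and values of single genes without an array where it takes them below the filter, were chosen after seeing the data, and the other alternatives before. The count of 0 probe sets past the threshold stayed at 0 on both array types with either other pseudocount, without the filter, under quantile normalization, median centring and cyclic loess, with both other variance models and with adjustment over both types together. The lowest adjusted p over these settings ranged from 0.0568 to 0.768 on 430A and, with the lowest 60% left out as well, from 0.0642 to 0.701 on 430B. On 430A 1 probe set passed with the lowest 60% left out, where fewer were tested. Without each array in turn the count ranged from 0 to 20 on 430A and from 0 to 30 on 430B, highest without double null sample 2. In those fits the lone array of a group is assumed to vary like the other group. Centred on the spike-in controls, the median log2 change moved from 0.00060 to -0.46 on 430A and from 0.0094 to -0.32 on 430B, and 21 and 8 probe sets passed, all lower. The cause was not tested, and this shift does not show that total RNA differed between the genotypes. The other scalings moved that median by less than 0.1. Counts of consistent 2-fold differences were 319 on 430A and 825 on 430B with a pseudocount of 1, 23 and 51 with the larger pseudocount, 81 and 181 with the lowest 60% left out, and 566 and 718 with spike-in centring. Without the filter there were 754 on 430B. A larger pseudocount and a stricter filter lower these counts by construction. Without each array they ranged from 227 to 349 and from 769 to 1024, since a lone array lies apart from the other group more often by chance. The number of lists past the threshold ranged from 4 to 12 on 430A and from 0 to 3 on 430B without each array, lowest without double null sample 1 and without Bax null sample 1. It was 1 on 430B without the filter, 1 with the lowest 60% left out, where the axon growth call was lost and the NGF-responsive list could not be tested, and 0 on both types with an estimated correlation. The correlation between array types was 0.187 with the larger pseudocount, 0.0762 without the filter and 0.246 with the lowest 60% left out, and it ranged from 0.0798 to 0.180 without each array. The cause was not tested for the lists and this correlation. The table held no detection calls, so how far dim signals limit these values was read only from the filters and pseudocounts above. With fewer than 5 measured members, some lists gave no value. On 430B these were the NGF-responsive and cell cycle lists without Bax null sample 1, the cell cycle list without double null sample 1, and both and apoptosis regulators with the lowest 60% left out. On 430A the cholinergic list gave none with the lowest 60% left out.

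The labels do not say that sample numbers are shared between genotypes. Deviations of same-numbered samples correlated at 0.345 on 430A and 0.0929 on 430B, and with 2 pairs this does not pair them. With the number as a replicate block, 2 probe sets passed on 430A, both lower, and 101 on 430B, 38 higher and 63 lower. That fit leaves little from which to estimate the spread, so these counts are not evidence of single-gene differences. The block ended the call of the muscle list (adjusted p = 0.067) and of no other list.

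The list means below had another sign than under the settings used, and the cause was not tested except for spike-in centring, which moves all genes of an array alike. Spike-in centring gave -0.37 for sympathetic transcription factors, -0.30 for injury response, -0.34 for apoptosis regulators, -0.22 for ribosomal proteins, -0.26 for cell cycle, -0.46 for satellite glia, -0.37 for fibroblast markers, -0.44 for endothelial markers, -0.18 for macrophage markers, -0.40 for lymphocyte and related markers, -0.16 for skeletal muscle markers, -0.39 for carotid body markers and -0.45 for neighbours of Ngf on 430A, and -0.24 for axon guidance and -0.16 for apoptosis regulators on 430B. Of these lists, ribosomal proteins, cell cycle, macrophage markers and skeletal muscle markers had been called higher. Relative to other genes they still passed as higher in camera (adjusted p = 0.031, 0.0062, 0.0020 and 0.0040). These sign changes follow from the shift of all values and leave the direction relative to other genes as it was. Whether the lists were higher or lower in absolute terms depends on the scaling and was not tested. Without the filter the means were 0.0039 for receptors and channels, -0.0022 for apoptosis regulators and -0.036 for endothelial markers on 430A, and 0.081 for catecholamine genes and 0.014 for neighbours of Ngf on 430B. With the lowest 60% left out they were 0.12 for BMP response, -0.018 for satellite glia, -0.10 for endothelial markers, -0.065 for lymphocyte and related markers and -0.018 for neighbours of Ngf on 430A, and 0.022 for receptors and channels on 430B. The larger pseudocount gave -0.011 for satellite glia and -0.0061 for endothelial markers on 430A, and a pseudocount of 1 gave 0.0082 for receptors and channels on 430B. Quantile normalization gave -0.0027 for satellite glia on 430A, and the mean of all kept probe sets 0.0043 for SRF targets and -0.0016 for satellite glia on 430A.

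Without each array in turn, list means that changed sign ranged on 430A from -0.13 to 0.028 for neurotrophin signalling, -0.14 to 0.021 for catecholamine genes, -0.28 to 0.0061 for immediate early genes, -0.26 to 0.18 for SRF targets, -0.15 to 0.023 for BMP response, -0.15 to 0.16 for satellite glia, -0.074 to 0.11 for endothelial markers, -0.13 to 0.15 for lymphocyte and related markers, -0.22 to 0.62 for skeletal muscle markers and -0.029 to 0.054 for neighbours of Ngf. On 430B they ranged from -0.42 to 0.058 for neurotrophin signalling, -0.11 to 0.11 for catecholamine genes, -0.086 to 0.28 for axon guidance and -0.18 to 0.022 for neighbours of Ngf. Of these, only the muscle list had been called. Single genes ranged from -0.44 to 0.39 for Bdnf, -0.46 to 1.599 for Rpl27a and -0.022 to 1.04 for Phox2a on 430A, and from -0.35 to 0.029 for Dbh, -0.88 to 0.095 for Ntrk3 and -1.74 to 0.16 for Pou4f1 on 430B. The cause was not tested. Single genes were not run with spike-in centring or cyclic loess. Over the other alternatives, 1465 values of single genes kept their direction and side of the threshold, 43 moved past it and 7 changed sign. Without some array 12 of the 112 gene values fell below the filter. Counted with those 12, 52 of 112 shrank by over 1.5 times or changed sign without 1 of the arrays. Of the list values 573 kept both, 48 lost their call, 15 of them with an estimated correlation, 7 gained one and 53 changed sign, 15 of them under spike-in centring.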

Other observations

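Ntrk2, a neurotrophin receptor gene of the neurotrophin and growth factor list, was singled out after its values were seen. The probe sets that stood for it had log2 changes of 0.06 ± 0.29 on 430A and 0.20 ± 0.29 on 430B. Its 6 kept probe sets disagreed, from -2.21 to 0.48, and none passed the threshold.

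On 99 probe sets present on both array types, arrays that carry the same sample name matched best in 4 of 4 cases. The correlations of their deviations across probe sets were 0.713 and 0.531 for the Bax null samples and 0.626 and 0.534 for the double null samples, and the highest between differently named arrays was 0.344.

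The B1 repeat control had signals on 430A of 3228 in Bax null sample 1 and 4613 in double null sample 1, and of 1068 and 949.5 in the samples numbered 2. Xist, the RNA of the inactive X chromosome, had signals on 430A of 740.1 and 1073 in Bax null samples and of 122.1 and 1456 in double null samples. The lowest, 122.1, was in double null sample 1, the array without which Th, Coro1a and the glycolysis and fat cell lists shrank. The labels do not give the sex of the samples, and its balance between the genotypes was not tested.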
